A study of Homo sapiens with 36 samples.

How the data were processed

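RNA was measured by sequencing in 36 libraries of H9 cells, an established line of human embryonic stem cells, that had been differentiated into neural crest, melanoblasts or melanocytes. The cells were either wild type (WT) or a triple knockout (3xKO) with CDKN2A (the gene of p16) and RB1 among its targets, and they carried a doxycycline-inducible BRAFV600E cassette that was switched on for 72 h (dox) or left off (control). Per the labels, about the same number of cells was collected per sample in Trizol, RNA was isolated with a Qiagen kit, and libraries followed standard Illumina protocols. A protocol text common to every sample says that melanoblasts were replated on day 11 after cell sorting and that melanocytes were infected on day 40 with a lentivirus carrying ATAD2 or Tomato. The labels do not say which libraries, if any, this applies to.

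The deposited table held whole-number read counts per gene, not scaled, for 18668 genes in 36 columns, all of which were matched to a label. Per the submitters' processing notes the steps involved FastQC, Trimmomatic, STAR, DESeq2 and the genome build GRCh38, with no versions or roles. The program that counted reads and the annotation it used are not given in the sources used here. Ensembl identifiers of 18648 genes were found in GENCODE 29, where 18587 were protein coding. The 20 genes without an entry and 22 rows with a repeated symbol stayed in the table. The columns carry a number of their own but no replicate number, so libraries of a group are lettered A to D in column order, and the labels pair no dox library with a control. Library totals ran from 26819331 to 39374336 counts, and the 10 most abundant genes took 5.74% to 16.5% of a library. Counting error at this depth is small for genes above about 1 CPM. Genes near 0.1 CPM rest on a few counts per library.

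Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3, in 1 model with a mean for each of the 12 groups. The default filter on low counts by group left 15961 genes. Each comparison was a contrast of group means, with Benjamini-Hochberg adjustment over those genes and a threshold of 0.05. Fold changes are log2 values with their standard error, and levels are CPM (counts per mega-count of the library after TMM scaling), given as mean and SD over the libraries of a group. There were 19 contrasts, of which 13 compared 2 groups and the rest were interactions. The 13 comprised steps between stages in WT control and in 3xKO dox cells, 3xKO against WT within each stage in control cells, and dox against control within each genotype and stage. The interactions asked whether the dox response differed between genotypes or, in 3xKO cells, between stages. A group of 2 libraries, as in WT neural crest control, takes its spread from the whole model.

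A set of 27 gene lists was fixed before the data were examined, together with the contrasts, the rule for named genes and the first set of alternative settings. The lists were neural crest, melanocyte lineage and pigmentation, output of the MAPK pathway, AP-1, DNA damage response and growth arrest, E2F targets, G2/M cell cycle, senescence-associated secretion, dedifferentiated melanoma, chromatin regulators, pluripotency, CNS progenitor, neuron, Schwann lineage, mesenchyme and fibroblast, epithelium and placode, endothelium, muscle, interferon response, antigen presentation, integrated stress and unfolded protein response, cholesterol biosynthesis, glycolysis and hypoxia, mitochondrially encoded genes, HOX, TGF-beta and WNT targets, and extracellular matrix and adhesion. Some genes stand in more than 1 list. Each list was tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, log2 CPM with prior count 2), adjusted over the 27 lists within a comparison. Camera was rerun with an estimated correlation, and that adjusted p is printed beside calls it ended. Members were counted as called over all genes tested and as called when adjusted over the list alone.

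Named genes followed a rule. For each comparison it took the 8 genes with the highest and the 8 with the lowest fold change among called genes at 5 CPM or more in at least 1 group and with every library of 1 group above every library of the other, up to 4 members of a list led with by smallest adjusted p plus members going against their list, and 22 key genes whatever their result. Sex-linked marker genes and genes without an approved-style symbol were left out. Results of some genes, a targeted gene among them, are not reported here. Gene positions are those of GENCODE 29 on GRCh38.

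The first set of alternative settings held RLE and upper-quartile scaling, no filter and a stricter filter on low counts (1 CPM and a mean of 10 counts), DESeq2 1.42.0, a model holding only the compared groups, each library left out in turn, and for lists an estimated correlation and fry. Settings chosen after the data were seen were the sum of 6 pairs of libraries that differed least, all neural crest or melanoblasts, a covariate for a split of neural crest and melanoblast libraries, a pairing of 3xKO melanocyte libraries in column order, leaving out the 8 libraries on the smaller side of that split, leaving out the 3xKO melanocyte library of each arm farthest from its group, and offsets that took out each library's trend on transcript GC content in 20 bins. The split came from the sign of the first component of deviations from group means within a genotype. Overlaps between dox responses used Fisher's exact test. Other splits of the libraries were fitted with the same model. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

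The model was tested on simulated counts for 5 comparisons. Each gene was drawn on its own around a mean shared by the 2 groups, with known genes changed. Of genes changed 4-fold, 84.85% to 87.88% were recovered. For genes changed 2-fold the share ran from 7.46% to 25.37%, and at 1.5-fold from 1.49% to 4.48%, with 0 to 7 false calls, so gene-wise counts miss most changes of 2-fold or less. Simulated lists of 25 genes changed 1.5-fold gave camera p from 1.20e-09 to 5.05e-13, and unchanged lists gave p from 0.305 to 0.858. Reads of the BRAF transgene could not be separated from those of the endogenous gene in counts per gene, and CDKN2A counts pool its 2 products. Values of multi-copy and closely related genes (HLA, CXCL, IFIT and mitochondrial genes with nuclear copies) depend on how shared reads were assigned, which is not given.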

Results

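RNA was sequenced from 36 libraries in 12 groups. The groups crossed 2 genotypes, 3 stages and the presence or absence of dox. The starting cells were H9, an established human embryonic stem cell line. Neural crest is the embryonic population from which pigment cells arise, melanoblasts are its committed pigment precursors, and melanocytes are the mature pigment cells. The 3xKO cells were built to lack 3 tumour suppressors, CDKN2A and RB1 among them, and dox switched on BRAFV600E, an always-active form of a kinase in the MAPK pathway. By its title the series asks how the chromatin state of a developmental stage bears on whether a cell can respond to a melanoma oncogene. WT neural crest held 4 dox and 2 control libraries, and each of the other groups held 3 libraries. In units of mega-counts (M), library totals were 31.91 to 33.83 M in WT neural crest control and 28.72 to 36.48 M with dox. WT melanoblasts had 29.39 to 33.99 M (control) and 32.39 to 33.34 M (dox), and WT melanocytes 28.64 to 34.07 M (control) and 32.36 to 39.37 M (dox). For 3xKO cells the control and dox totals were 26.82 to 32.43 M and 28.84 to 32.07 M in neural crest, 27.34 to 34.84 M and 28.25 to 30.90 M in melanoblasts, and 29.27 to 34.69 M and 30.88 to 38.10 M in melanocytes. Mitochondrially encoded transcripts took 9.81% ± 0.598 (SD, n = 3) of counts in WT melanocyte controls, 7.502% ± 2.34 in 3xKO melanocyte controls, and under 3% on average in every neural crest and melanoblast group, where the highest group mean was 2.84% ± 0.545 (n = 4).

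**Figure D1:**
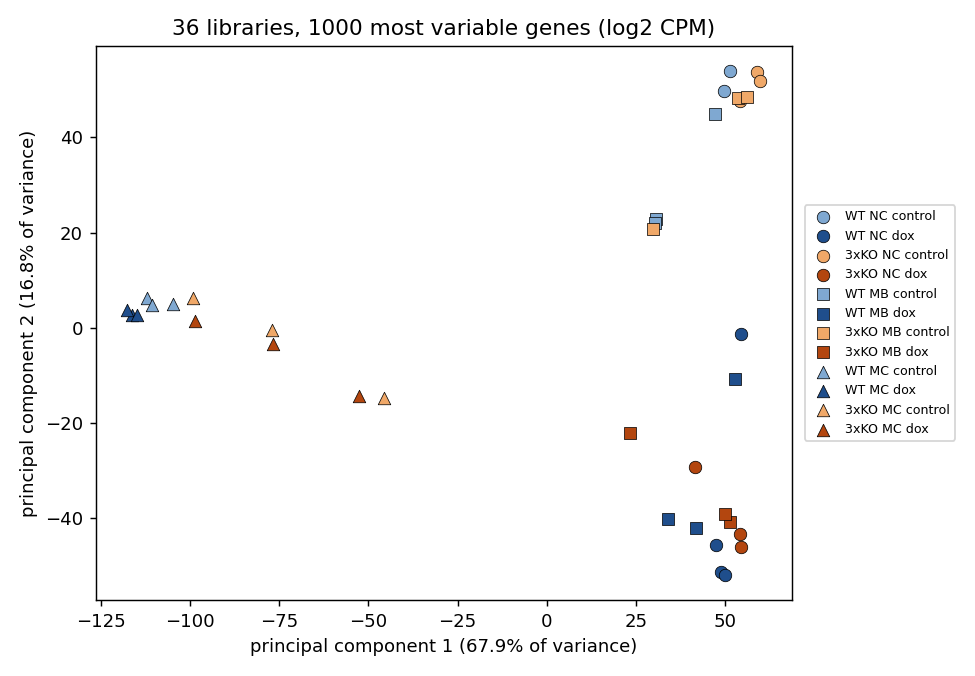
Each point is 1 of the 36 libraries placed by the first 2 principal components of log2 CPM over the 1000 most variable genes (PC1 67.9% of variance, PC2 16.8%), with colour and marker for stage, genotype and dox. Melanocytes lie apart from neural crest and melanoblasts along PC1, and PC2 parts dox from control in the latter 2 stages.

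Libraries of the same group were not all alike. Deviations from group means in WT neural crest and melanoblasts had 1 component that took 64.0% of their variance, and it set apart neural crest control B and dox D together with melanoblast control C and dox A. A component with 46.8% of the variance did so in 3xKO cells for neural crest control A and dox A and melanoblast control A and dox B. In 3xKO melanocytes the first component took 76.3%, with control B and dox B farthest out. The labels name no batch. Across genes the dox changes of the 2 sets correlated at r = 0.661 in WT neural crest, 0.690 in WT melanoblasts, 0.812 in 3xKO neural crest and 0.563 in 3xKO melanoblasts. The smaller sets hold 1 library per group, so no test could be run within them. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries. In what follows, ± is the standard error for a log2 change and the SD for a CPM level, p-values are adjusted values from edgeR's quasi-likelihood test for genes and from camera for lists, and n is 3 libraries per group unless stated.

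The targeted genes showed how the genotype appeared in RNA. RB1 (ENSG00000139687, chromosome 13, 48303726 to 48599436, plus strand), a brake on cell cycle entry, did not differ detectably between 3xKO and WT controls in neural crest (57.4 ± 3.31 against 58.5 ± 3.10 CPM, n = 2 for WT) or melanoblasts (53.1 ± 3.93 against 49.1 ± 6.39 CPM). It was higher in 3xKO melanocytes, with a log2 change of 2.01 ± 0.30 (47.8 ± 23.2 against 11.9 ± 3.56 CPM, adjusted p = 5.14e-06). With offsets for GC content that change of RB1 was 0.48 ± 0.14 (adjusted p = 0.0089). CDKN2A (ENSG00000147889, chromosome 9, 21967753 to 21995301, minus strand), which encodes p16 and p14ARF, was higher in 3xKO cells. In neural crest controls its level was 8.56 ± 1.48 against 0.0645 ± 0.0179 CPM, in melanoblast controls 5.998 ± 0.850 against 0.103 ± 0.0702 CPM, and in melanocyte controls 231 ± 65.6 against 87.5 ± 11.4 CPM. The call in melanocytes (1.399 ± 0.50, adjusted p = 0.0206) ended without WT control B or C or 3xKO control B (adjusted p = 0.0687, 0.0598 and 0.0838). With dox the levels in 3xKO and WT were 22.9 ± 2.85 and 8.53 ± 5.54 CPM (n = 4) in neural crest, 17.4 ± 2.95 and 10.5 ± 10.5 CPM in melanoblasts, and 274 ± 122 and 104 ± 5.15 CPM in melanocytes. The labels do not say how the genes were disrupted, and a disrupted gene can still yield RNA. RB1 with dox was 31.7 ± 5.31, 33.7 ± 1.68 and 43.1 ± 15.7 CPM in 3xKO and 30.1 ± 2.03 (n = 4), 30.2 ± 4.99 and 4.23 ± 1.84 CPM in WT.

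BRAF (ENSG00000157764, chromosome 7, 140719327 to 140924928, minus strand), whose counts pool the endogenous gene with any transgene reads, rose with dox in WT neural crest and melanoblasts. Its level went from 32.3 ± 9.09 (n = 2) to 121 ± 11.9 CPM (n = 4) in WT neural crest, a log2 change of 1.91 ± 0.37 (adjusted p = 6.69e-04). In WT melanoblasts it went from 30.8 ± 12.6 to 99.5 ± 9.13 CPM, 1.69 ± 0.33 (adjusted p = 6.75e-04). It was not called in 3xKO neural crest (0.71 ± 0.32, adjusted p = 0.152) or 3xKO melanoblasts (0.90 ± 0.32, adjusted p = 0.0747). There the libraries of a group differed. In 3xKO neural crest dox B and C were at 55.9 and 64.5 CPM and dox A at 25.5 CPM, with controls at 28.2 to 32.4 CPM. In 3xKO melanoblasts dox A and C were at 68.9 and 64.2 CPM and dox B at 35.1 CPM, with controls at 28.2 to 31.2 CPM. Neural crest dox A and melanoblast dox B both belong to the smaller set of libraries. Within the larger and smaller sets the log2 difference of BRAF was 2.18 and 1.77 in WT neural crest, 2.14 and 0.99 in WT melanoblasts, 1.08 and -0.35 in 3xKO neural crest, and 1.10 and 0.32 in 3xKO melanoblasts. Melanocytes had less BRAF RNA and no called change, at 5.62 ± 0.252 against 6.70 ± 0.449 CPM in WT (-0.25 ± 0.33, adjusted p = 0.861) and 26.1 ± 9.26 against 19.3 ± 9.58 CPM in 3xKO (0.44 ± 0.32, adjusted p = 1). ATAD2 (ENSG00000156802, chromosome 8, 123319850 to 123416350, minus strand), a bromodomain ATPase of chromatin that a lentivirus named in the protocol carries, was not called in any of the 6 dox comparisons (adjusted p from 0.434 to 1).

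**Figure D2:**
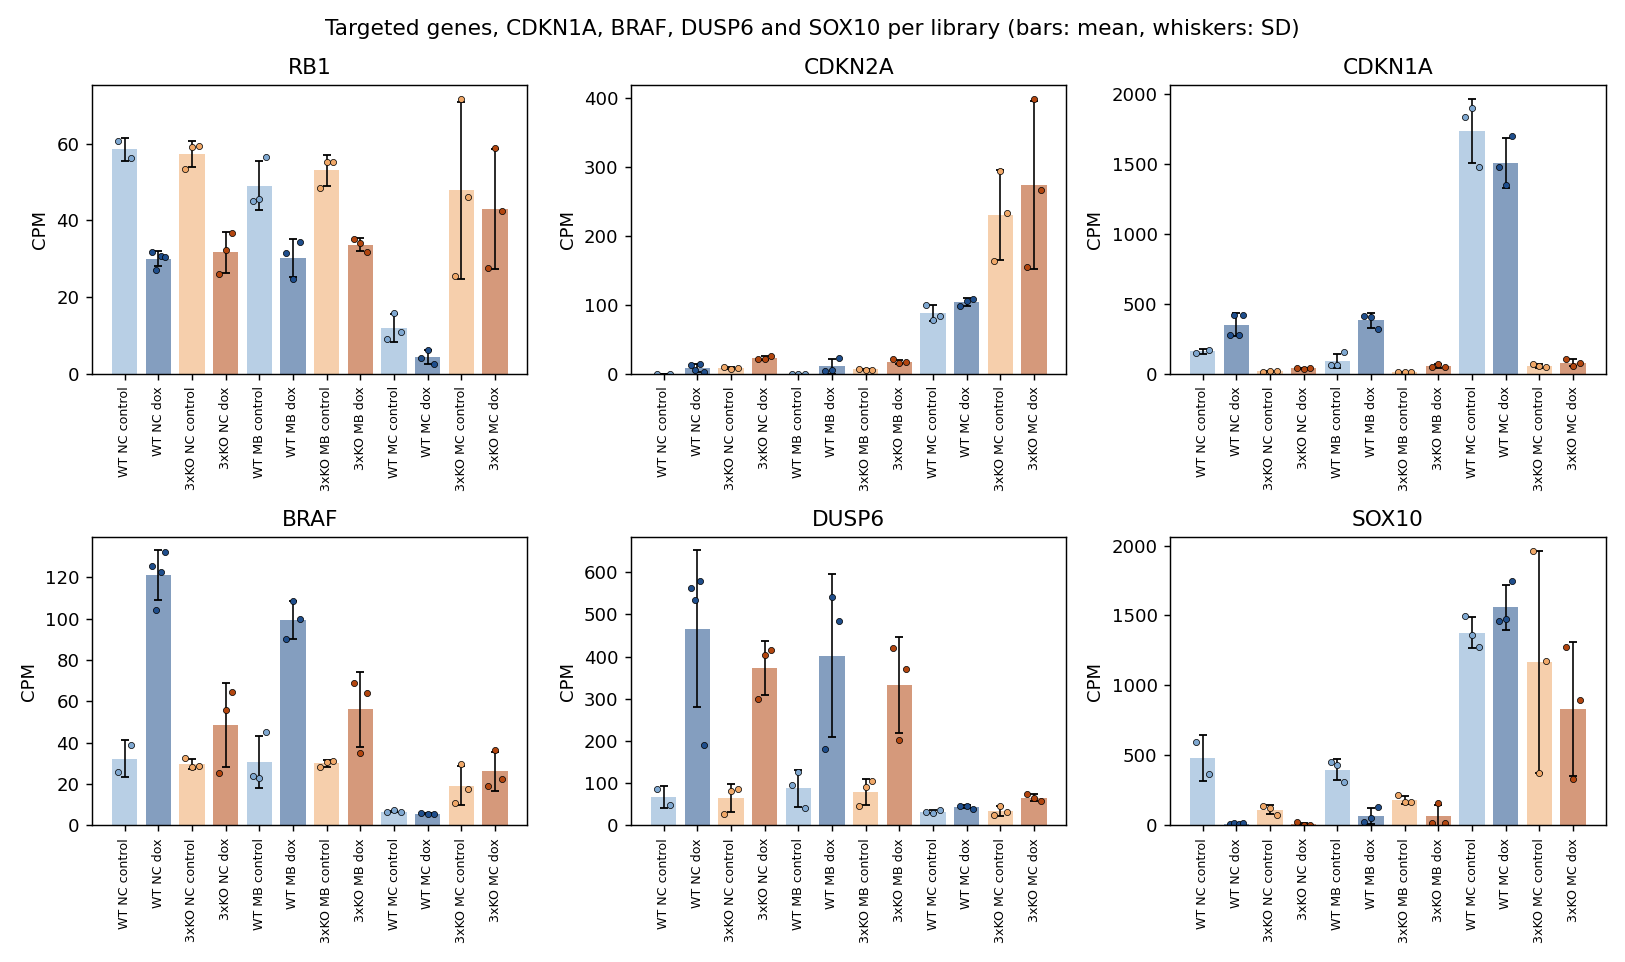
Bars are the group mean CPM of RB1, CDKN2A, CDKN1A, BRAF, DUSP6 and SOX10 (linear axes from 0), error bars the SD, and points the single libraries of the 12 groups. CDKN1A is lower in every 3xKO group than in WT, RB1 is not, and BRAF and DUSP6 stand higher with dox in neural crest and melanoblasts than in melanocytes.

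The step from neural crest to melanoblasts in WT controls (3 against 2 libraries) asked what marks pigment commitment. Pigment cell genes rose. MLANA, a melanosome protein, changed by 6.70 ± 1.19 log2 (291 ± 224 against 2.80 ± 1.64 CPM, adjusted p = 0.00881), and TYR, the enzyme that starts melanin synthesis, by 7.07 ± 1.33 (adjusted p = 0.0116). DCT, a later melanin enzyme, changed by 7.27 ± 1.44 (779 ± 600 against 5.04 ± 2.25 CPM) and MITF, the master regulator of the lineage, by 3.93 ± 0.94 (150 ± 95.6 against 9.81 ± 2.06 CPM, adjusted p = 0.0408). Of 30 genes of melanocyte lineage and pigmentation, 14 rose and 0 fell, or 21 rose when adjusted over the list alone (camera adjusted p = 1.96e-36, and 0.0311 with an estimated correlation). PMEL, which builds melanosome fibrils, was not called (3.09 ± 1.11, adjusted p = 0.259). Further genes that rose were IGFBP7, SNAI2, TWIST2 and CDH3, and those that fell included the transcription factor FOXD2, HEY2 and the keratin KRT8 (-1.94). Neuron genes stood lower as a list with 0 of 24 members called (median -1.80, camera adjusted p = 1.03e-09, and adjusted p = 0.395 with an estimated correlation). In all, 99 genes were higher and 17 lower. This count was set by single libraries, with 0 genes without neural crest control A, 12 without neural crest control B, 16 and 21 without melanoblast control A and B, and 1028 without melanoblast control C. None of the 23 named genes called kept its call in every one of these fits (edgeR; 1464 genes had an unadjusted p under 0.05 and DESeq2 called 357). A model of these 2 groups alone, or with close pairs of libraries summed, called 0 genes, and one without the libraries that stood apart called 1398.

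From melanoblasts to melanocytes in WT controls, cells lost the transcripts of division and gained those of pigment. MKI67, a marker of cycling cells, fell by 7.89 on the log2 scale (SE 0.73), from 222 ± 8.79 to 0.931 ± 0.150 CPM, and all 28 tested G2/M genes fell (camera adjusted p = 6.26e-09). E2F targets, the genes of DNA replication, had 27 of 32 members lower and 1, the uracil glycosylase UNG, higher (adjusted p = 9.65e-05). OCA2, a melanosome transporter, rose by 9.68 ± 0.56 (1601 ± 57.0 against 1.95 ± 0.613 CPM), PMEL by 4.34 ± 0.99 and TYR by 3.93, within a pigmentation list with 17 genes higher and 5 lower (adjusted p = 0.0107). The cell cycle inhibitors CDKN2A (9.65 ± 0.79, from 0.103 CPM) and CDKN1A (4.27 ± 0.32, 1739 ± 229 against 90.2 ± 53.4 CPM) rose. ATAD2 fell by 5.75 (SE 0.65), from 48.3 ± 1.25 to 0.895 ± 0.264 CPM (adjusted p = 1.06e-08), as 1 of 29 chromatin regulators that fell, among them EZH2 (-4.93), CHD7 (-3.93) and TET1 (-4.92). The list had 7 genes that rose, including CBX7, HMGA1 and PHF19 (adjusted p = 0.00578). All 13 mitochondrially encoded genes rose (median 2.73, adjusted p = 2.69e-05). So did 16 of 23 stress response genes (adjusted p = 4.33e-05) and 12 of 17 antigen presentation genes (adjusted p = 4.00e-04). Rises also came in 14 of 23 glycolysis and hypoxia genes with 1 lower (adjusted p = 0.00758) and 15 of 29 MAPK output genes with 4 lower (adjusted p = 0.0137). AP-1 had 8 of 11 genes higher and 1 lower (adjusted p = 0.0304). None of these list calls held with an estimated correlation (adjusted p from 0.321 to 0.723). The pigmentation call ended without melanoblast control C (adjusted p = 0.0717) and that of AP-1 without melanoblast control B (adjusted p = 0.0638). In all 5467 genes were higher and 6646 lower. RLE and upper-quartile scaling moved the median of all genes by 0.11 and -0.14. Changes followed transcript GC content (Spearman 0.62 across genes, which are not independent replicates). GC offsets kept 7213 of 12113 calls. RB1 (-2.05 ± 0.30 to 0.47, adjusted p = 0.00513), MDM2 and SPRY4 were called the opposite way.

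In 3xKO cells with dox, no single gene was called between neural crest and melanoblasts. SOX10, a master regulator of neural crest and pigment cells, had a log2 difference of 2.70 ± 0.77 (adjusted p = 0.603), and PHLDA3, an AKT inhibitor, had the smallest adjusted p (1.17 ± 0.22, 0.222). edgeR called 0 genes, with 581 at an unadjusted p under 0.05, DESeq2 called 13, all higher, and leaving out melanoblast dox C gave 1. Glycolysis and hypoxia genes stood higher as a list with 0 members called (median 0.47, camera adjusted p = 2.60e-07, and adjusted p = 0.565 with an estimated correlation). Pigmentation genes did so too (median 0.73, adjusted p = 1.12e-04, and adjusted p = 0.565 with an estimated correlation), a call that ended without melanoblast dox B (adjusted p = 0.554).

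From melanoblasts to melanocytes with dox, 3xKO cells raised pigment genes. TYR rose by 9.92 ± 1.22 (1237 ± 228 against 1.28 ± 1.15 CPM), MLANA by 9.74, TYRP1 by 10.35 (SE 1.303) and OCA2 by 9.37 ± 0.56. Of the 30 pigmentation genes 24 rose and 1 fell, or 26 and 1 when adjusted over the list alone (camera adjusted p = 8.88e-12). G2/M genes fell in 25 of 28 cases (adjusted p = 1.12e-08), with MKI67 at -4.13 ± 0.59 (17.6 ± 18.1 against 310 ± 83.4 CPM), and E2F targets in 21 of 32 (adjusted p = 2.61e-04). MAPK feedback regulators were lower, DUSP6 by -2.34 and SPRY4 by -2.02. ATAD2 changed by -3.56 ± 0.56 (7.77 ± 7.30 against 92.1 ± 10.4 CPM). Interferon response genes rose in 16 of 22 cases (adjusted p = 8.82e-05), antigen presentation in 13 of 17, where CD74 fell (adjusted p = 2.39e-04), and stress response genes in 18 of 23 (adjusted p = 1.31e-05). Cholesterol biosynthesis had 12 of 21 genes lower and 2 higher (adjusted p = 9.31e-04), glycolysis and hypoxia 14 of 23 lower and 1 higher (adjusted p = 0.00271), and dedifferentiated melanoma 12 of 25 lower and 1 higher (adjusted p = 0.00450). None of these list calls held with an estimated correlation (adjusted p from 0.331 to 0.572). In all 4577 genes were higher and 4768 lower, and 140 of 157 named calls held without any 1 library. Changes followed GC content (Spearman 0.40), and GC offsets kept 6862 of 9345 calls. Upper-quartile scaling moved the median of all genes by -0.11.

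3xKO against WT cannot tell genotype from clone or batch at any stage. In neural crest controls (3 against 2 libraries) genes of DNA damage response and growth arrest fell. PHLDA3 changed by -4.67 ± 0.26 (1.03 ± 0.157 against 26.3 ± 2.73 CPM, adjusted p = 1.17e-12), CDKN1A, the p21 cell cycle inhibitor, by -3.25 ± 0.32 (16.7 ± 2.03 against 159 ± 19.1 CPM, adjusted p = 4.99e-07), the exonuclease AEN by -2.45 ± 0.23 and RPS27L by -2.10 ± 0.23. Of 32 genes of that list 15 fell and 0 rose, and 25 fell when adjusted over the list alone (median -1.38, camera adjusted p = 1.14e-50, and 3.23e-08 with an estimated correlation). PTCHD4 (-5.31 ± 0.58), the receptor EDA2R (-4.65 ± 0.62) and smooth muscle actin ACTA2 (-5.13 ± 0.80, 0.453 ± 0.141 against 15.98 ± 0.377 CPM) also fell, while CDKN2A rose (6.97 ± 0.94, adjusted p = 6.42e-05). E2F targets stood higher as a list (median 0.73, camera adjusted p = 9.13e-12) with 1 called, E2F1 (1.56 ± 0.35, adjusted p = 0.0224), and 6 when adjusted over the list alone. G2/M genes did so with 0 called (median 0.65, adjusted p = 1.24e-07), and cholesterol genes with 1, INSIG1 (median 0.67, adjusted p = 3.27e-09). These 3 calls were lost with an estimated correlation (adjusted p = 0.402, 0.4999 and 0.402). HOX genes stood lower with 0 of 24 called (median -4.45, adjusted p = 1.21e-08, and adjusted p = 0.402 with an estimated correlation), but without WT control B, 1 of the libraries that stood apart, that call ended (adjusted p = 0.308). In total 56 genes were higher and 82 lower. The count fell to 47 and 30 without WT control A and B and to 86, 86 and 55 without 3xKO control A, B and C. Of the named genes called, 9 of 27 kept their calls in every one of these fits, CDKN2A, PHLDA3, CDKN1A, AEN, RPS27L, PTCHD4, EDA2R and ACTA2 among them. Other settings gave 30 (close pairs summed) to 685 genes (only these 2 groups).

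In melanoblast controls the same list fell. PHLDA3 changed by -4.18 ± 0.24 (1.38 ± 0.0416 against 25.2 ± 4.40 CPM, adjusted p = 3.73e-12), CDKN1A by -2.95 ± 0.31 (11.7 ± 2.35 against 90.2 ± 53.4 CPM) and AEN by -2.32 ± 0.21, and 19 of 32 targets fell and 0 rose, or 24 when adjusted over the list alone (median -1.31, camera adjusted p = 9.40e-27, and 1.03e-05 with an estimated correlation). Higher genes included CDKN2A (5.78 ± 0.73), the natriuretic peptide receptor NPR1 (3.81 ± 0.52), the metallothionein MT2A (3.36 ± 0.48, 52.7 ± 31.9 against 5.11 ± 2.65 CPM), the Polycomb subunit PHF19 (1.57 ± 0.25, adjusted p = 3.44e-04) and the antiviral membrane protein BST2 (2.51 ± 0.42). Pigmentation genes stood lower, with 7 of 30 called, or 9 when adjusted over the list alone (median -1.04, adjusted p = 3.91e-07, and adjusted p = 0.601 with an estimated correlation); TYR itself was at -2.31 ± 0.87 (adjusted p = 0.125). Neuron genes stood higher with 0 of 24 called (median 1.02, adjusted p = 0.0150, and adjusted p = 0.673 with an estimated correlation), a call that ended without WT control A or B or 3xKO control B or C (adjusted p = 0.181, 0.180, 0.102 and 0.180). Median log2 CPM of pigmentation and neuron genes was 3.52 and 5.62 in 3xKO control B, 3.25 and 5.71 in C, and 5.96 and 2.96 in A. In WT it was 6.18 and 2.39 in control A, 6.04 and 2.45 in B, and 4.06 and 4.74 in C. Fits without the set-apart 3xKO A and WT C compare unlike levels of both lists. Cholesterol genes were higher with 4 of 21 called and 13 when adjusted over the list alone (adjusted p = 3.54e-08, and adjusted p = 0.554 with an estimated correlation), INSIG1 (1.28 ± 0.21) and MSMO1 (1.36 ± 0.26) among them. Glycolysis and hypoxia genes had 3 of 23 higher and 9 when adjusted over the list alone (adjusted p = 3.54e-08, and adjusted p = 0.597 with an estimated correlation). E2F targets had 2 higher, SLBP (0.91 ± 0.18) and CDT1 (1.17 ± 0.30), with a list call (adjusted p = 1.52e-05, and adjusted p = 0.673 with an estimated correlation) that ended without WT control C (adjusted p = 0.0548). The HOX median was -4.80 with 0 genes called (adjusted p = 0.00757, and adjusted p = 0.673 with an estimated correlation) and 1.32 without the libraries that stood apart. In all 390 genes were higher and 372 lower. The count was 203, 206 and 1693 without WT control A, B and C and 318 and 362 without 3xKO control B and C. Of 55 named calls 25 held in every such fit. Other settings gave 51 (close pairs summed) to 3344 genes (without the libraries that stood apart).

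In melanocyte controls the 2 genotypes differed most, with 5478 genes higher and 2883 lower in 3xKO. Fold changes followed transcript GC content across genes (Spearman -0.54; median GC 43.4% in higher and 56.5% in lower genes). With offsets for that trend 3279 genes were higher and 2402 lower, and 4181 of the 8361 calls were kept in the same direction. The antiviral genes of the interferon response were higher in 3xKO than in WT. OAS2, a sensor of viral RNA, rose by 9.04 ± 0.99 (89.2 ± 93.2 against 0.164 ± 0.0606 CPM), IFI44L by 10.77 ± 1.08, MX1 by 5.27 ± 0.56 and BST2 by 6.08 ± 0.46 (314 ± 127 against 4.61 ± 0.450 CPM, adjusted p = 3.98e-10). Of 22 interferon genes 21 rose and 0 fell (median 5.59, camera adjusted p = 1.48e-13, and adjusted p = 0.217 with an estimated correlation). Antigen presentation had 11 of 17 genes higher, such as B2M (3.88 ± 0.38, 815 ± 407 against 55.3 ± 9.45 CPM) and PSMB9 (7.601), and CD74 lower (-2.45 ± 0.47); that call (adjusted p = 0.00481, and adjusted p = 0.755 with an estimated correlation) ended without 3xKO control A (adjusted p = 0.126). Cell cycle genes were higher too, with 28 of 28 G2/M genes (median 3.08, adjusted p = 6.83e-12) and 24 of 32 E2F targets (adjusted p = 8.82e-06), both at adjusted p = 0.755 with an estimated correlation. MKI67 stood at 17.6 ± 18.2 against 0.931 ± 0.150 CPM (4.24 ± 0.64) and ATAD2 at 12.3 ± 14.3 against 0.895 ± 0.264 CPM (3.78 ± 0.62, adjusted p = 1.50e-05), each with an SD above its 3xKO mean. Damage response and growth arrest genes fell in 17 of 32 cases, with CDKN1A at -5.001 ± 0.33 (54.3 ± 11.9 against 1739 ± 229 CPM), EDA2R at -7.15 ± 0.72 and SPATA18 at -5.03 ± 0.41; 3 rose, ASCC3 (1.82), RRM2B (0.96) and SESN1 (0.69). Adjusted over the list alone the numbers were 18 and 3 (adjusted p = 7.15e-09, and 0.0206 with an estimated correlation).

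Other lists held called genes in the same comparison, some without a list call. Glycolysis and hypoxia genes fell in 14 of 23 cases, among them GAPDH (-1.89 ± 0.23) and PGK1 (-1.75), and mitochondrially encoded genes in 6 of 13 (adjusted p = 2.40e-06 and 0.00272, both at adjusted p = 0.755 with an estimated correlation). Chemokines CXCL8 (9.73 ± 1.49), CXCL1 (4.32 ± 0.50) and CXCL2 (4.73) rose among 13 of 23 senescence-associated secretion genes, whose list was not called (adjusted p = 0.0805). Mesenchyme and fibroblast genes had 12 of 19 higher, such as PDGFRA (5.21) and THY1 (4.63 ± 0.44), and 2 lower, ACTA2 (-3.72) and TAGLN (-2.15), with no list call (adjusted p = 0.501). Their level was 1.89, 7.07 and 4.76 log2 CPM in 3xKO control A, B and C and 3.09 to 3.45 in WT controls. Chromatin regulators had 27 of 44 higher, including SMARCA2 (1.83), and 5 lower, including SMARCA4 (-1.07), also with no list call (adjusted p = 0.115). The pigmentation list did not shift (8 higher, 1 lower, median 0.16, adjusted p = 0.966). Cyclin D1 (CCND1) fell by 2.09 on the log2 scale (SE 0.25). The 3xKO groups held a wide spread here, since 3xKO control B stood far from the other two. Without any 1 library 104 of 141 named calls held. The direction of 3 genes turned with offsets for GC content, RRM2B (-0.32), SESN1 (-0.58) and the sterol enzyme SC5D (-0.24), and a model of these 2 groups alone called 4747 genes.

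**Figure D3:**
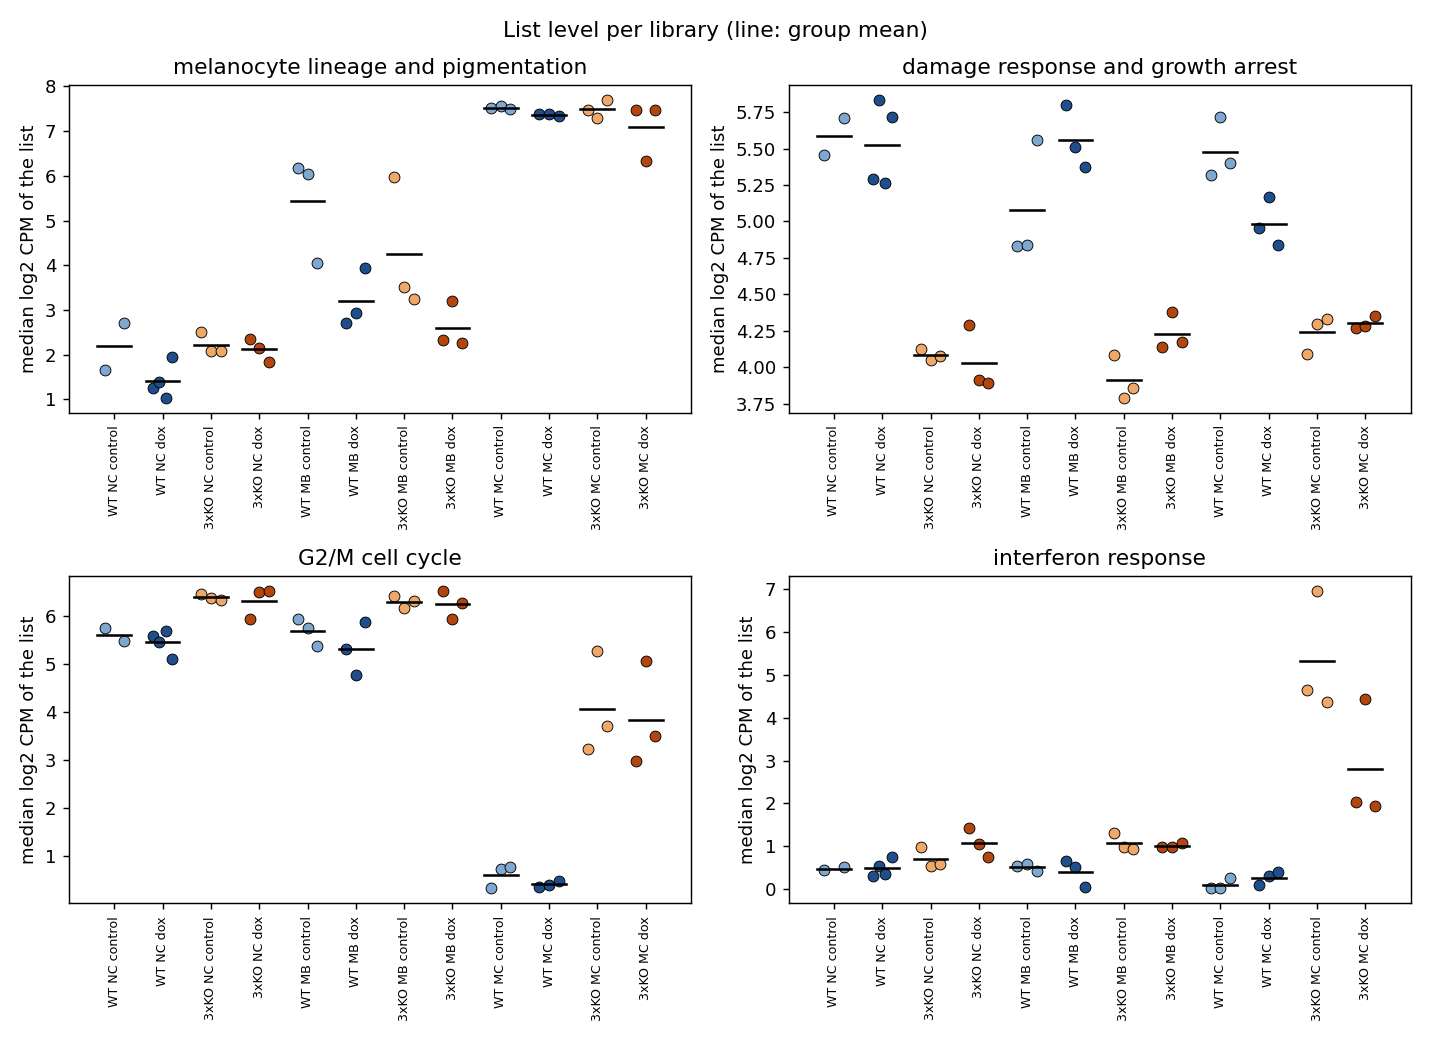
Each point is the median log2 CPM of a gene list in 1 library, by group, for pigmentation, damage response and growth arrest, G2/M cell cycle and interferon response. Interferon genes stand highest in 3xKO melanocyte controls and lower with dox, and G2/M genes are lowest in WT melanocytes.

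Dox in WT neural crest (4 against 2 libraries) came at the earliest stage. No group had dox without the cassette, so dox and BRAFV600E effects are not separable in any dox comparison. MAPK output genes rose. SPRY4, a feedback inhibitor of the pathway, changed by 3.78 ± 0.38 (485 ± 129 against 35.4 ± 9.07 CPM, adjusted p = 2.17e-07), IER3, an immediate early gene, by 5.38 ± 0.49 (adjusted p = 5.19e-08). The phosphatase DUSP6 changed by 2.78 ± 0.55 (466 ± 185 against 67.8 ± 25.9 CPM) and the transcription factor ETV4 by 2.92 ± 0.45. Of 29 MAPK genes 20 rose and 0 fell, or 21 and 1 when adjusted over the list alone (median 2.02, camera adjusted p = 1.25e-18, and 5.05e-07 with an estimated correlation). Identity genes of the crest and its neural derivatives fell. SOX10 changed by -5.31 ± 0.79 (12.2 ± 5.91 against 482 ± 162 CPM, adjusted p = 2.98e-05), FOXD3 by -5.63 ± 0.75, SOX2 by -5.91 ± 0.74 and the neurogenic factor NEUROG1 by -9.28 ± 1.26. Neuron genes had 9 of 24 lower and 0 higher (13 when adjusted over the list alone; median -2.94, adjusted p = 2.43e-11, and adjusted p = 0.239 with an estimated correlation). The median was -5.63 in the larger set of libraries and -0.74 in the smaller set. Dox D, which stood apart, had a list level of 4.09 log2 CPM, dox A, B and C had -1.24 to -0.17, and controls had 5.44 and 5.12. Schwann lineage genes had 9 of 17 lower and 0 higher (adjusted p = 2.02e-06, and adjusted p = 0.120 with an estimated correlation). The neural crest list split, with 12 of 24 lower and 7 higher, MSX1 (4.99) and MSX2 (6.04) among those that rose (adjusted p = 0.0166, and adjusted p = 0.353 with an estimated correlation). The homeobox gene LHX8 (9.045 ± 1.015, 159 ± 32.6 against 0.297 ± 0.0529 CPM) and the protease inhibitor PI15 (8.20 ± 0.89) were among the genes that rose most, and MMP1, a collagenase, stood at 14.3 ± 1.46 against 0.0387 ± 0.0180 CPM.

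Secreted and matrix genes rose in the same cells. Senescence-associated secretion had 10 of 23 genes higher, including IGFBP7 (4.63) and TIMP1 (1.67), and IGFBP5 lower (-3.81), or 13 and 1 when adjusted over the list alone (adjusted p = 1.73e-07, and adjusted p = 0.0580 with an estimated correlation). The dedifferentiated melanoma list had 8 of 25 higher, such as WNT5A (4.24) and SERPINE2 (2.28), and 1 lower (adjusted p = 0.00224, and adjusted p = 0.423 with an estimated correlation). Extracellular matrix and adhesion had 10 of 22 higher and 4 lower, with COL4A1 at 2.73 and MMP14 at 2.23 (adjusted p = 0.00277, and adjusted p = 0.261 with an estimated correlation). CDKN2A rose by 6.96 ± 0.93 and its neighbour CDKN2B by 4.78 ± 0.97, CCND1 rose by 2.09 ± 0.29, and CDKN1A by 1.14 ± 0.32 (adjusted p = 0.0131), which was not called without control A (adjusted p = 0.145) or control B (adjusted p = 0.0804). G2/M genes had 0 of 28 called (median -0.10, adjusted p = 0.732), with MKI67 at 165 ± 34.4 and 174 ± 5.35 CPM. In all 1158 genes were higher and 1384 lower. The count was 1216 and 1100 without control A and B, 4160 without dox D, and 1268 with close pairs summed. Of the named calls, 72 of 117 held without any 1 library.

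In 3xKO neural crest dox again raised MAPK output and lowered neuronal genes. SPRY4 changed by 2.35 ± 0.31 (adjusted p = 6.34e-06), DUSP6 by 2.52 ± 0.47 (372 ± 64.2 against 64.8 ± 32.95 CPM) and IER3 by 4.04 ± 0.39. EGR1, an immediate early transcription factor, changed by 4.89 ± 0.56 (354 ± 54.95 against 11.9 ± 13.5 CPM). Of 29 MAPK genes 22 rose and 0 fell, 23 when adjusted over the list alone (median 1.91, camera adjusted p = 1.31e-23, and 5.52e-08 with an estimated correlation). Senescence-associated secretion had 12 of 23 higher, with CXCL1 (2.97) and the EGFR ligand AREG (5.47), and IGFBP5 lower (-4.27), or 18 and 1 when adjusted over the list alone (median 2.56, adjusted p = 2.05e-11, and 0.00828 with an estimated correlation). Neuron genes fell in 14 of 24 cases, 17 when adjusted over the list alone, with NEUROD1 at -8.97 ± 1.57 (0.191 ± 0.112 against 96.4 ± 18.4 CPM), NHLH1 at -8.17 and ISL1 at -7.39 (adjusted p = 4.49e-14, and adjusted p = 0.175 with an estimated correlation). SOX10 fell by 3.51 on the log2 scale (SE 0.80; 9.98 ± 9.76 against 113 ± 33.04 CPM, adjusted p = 0.00290). Extracellular matrix genes had 9 of 22 higher and 1 lower (adjusted p = 3.76e-05, and adjusted p = 0.142 with an estimated correlation). TGF-beta and WNT targets had 8 of 21 higher and 0 lower (adjusted p = 0.00175, and adjusted p = 0.424 with an estimated correlation). The damage response and growth arrest list had 5 of 32 higher, such as CDKN1A (1.15 ± 0.29, 37.0 ± 3.46 against 16.7 ± 2.03 CPM) and TNFRSF10B (1.58), and 4 lower, such as SESN2 (-1.36), with no list call (adjusted p = 0.351). CDKN2B rose by 5.54 ± 0.86. MMP1 changed by 8.44 ± 0.80 (38.3 ± 4.69 against 0.109 ± 0.0695 CPM). In all 1110 genes were higher and 1279 lower. The count was 1529 without dox C, 749 with close pairs summed and 3703 in a model of these 2 groups. Among named calls 82 of 113 held without any 1 library.

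Dox responses of the 2 genotypes overlapped in neural crest. Higher genes shared 742 of 1158 and 1110, against 80.5 by chance, and lower genes 764 of 1384 and 1279, against 110.9. Log2 changes correlated across genes at Pearson r = 0.784, and 1 gene went in opposite directions. In melanoblasts the shared numbers were 591 higher (64.8 by chance) and 397 lower (51.8 by chance), with r = 0.725 across genes. Between neural crest and melanoblasts 720 higher and 648 lower genes were shared in WT and 660 and 633 in 3xKO (expected 58.8 to 93.4). Melanocytes shared few, with 3 higher genes (0.0102 expected) and 0 lower (1.82 expected) between genotypes and r = 0.0530.

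Dox in WT melanoblasts raised MAPK output and lowered pigment genes. SPRY4 changed by 3.29 ± 0.32 (404 ± 90.8 against 41.2 ± 13.6 CPM, adjusted p = 5.55e-08), IER3 by 5.28 ± 0.41 (adjusted p = 1.18e-09), DUSP6 by 2.19 ± 0.46 and FOSL1, an AP-1 subunit, by 4.07. Of 29 MAPK genes 22 rose and 0 fell, 25 when adjusted over the list alone (median 2.17, camera adjusted p = 7.25e-28, and 1.10e-08 with an estimated correlation). Pigmentation genes fell in 18 of 30 cases and rose in 0, or 24 when adjusted over the list alone (median -2.26, adjusted p = 2.03e-11, and adjusted p = 0.215 with an estimated correlation). DCT changed by -5.97 ± 1.12 (12.4 ± 12.6 against 779 ± 600 CPM), TYR by -5.32 ± 1.00 (2.78 ± 2.46 against 111 ± 83.2 CPM), PMEL by -3.87 ± 0.97 and MITF by -3.09 ± 0.76 (17.6 ± 12.2 against 150 ± 95.6 CPM, adjusted p = 0.00586). Senescence-associated secretion had 14 of 23 higher and 0 lower (median 2.06, adjusted p = 2.03e-11, and 0.00827 with an estimated correlation; 15 and 1 when adjusted over the list alone). The damage response and growth arrest list had 10 of 32 higher, including CDKN1A (2.08 ± 0.29, 381 ± 53.6 against 90.2 ± 53.4 CPM), PLK3 (1.96) and XPC (1.25), and 1 lower, with the same numbers when adjusted over the list alone (adjusted p = 4.57e-06, and 0.0454 with an estimated correlation). AP-1 had 5 of 11 higher, such as JUNB (3.19), and 8 when adjusted over the list alone (adjusted p = 1.76e-05, and adjusted p = 0.215 with an estimated correlation). The integrated stress and unfolded protein response had 11 of 23 higher, TRIB3 (2.54) among them (adjusted p = 2.81e-07, and adjusted p = 0.0785 with an estimated correlation). Keratins KRT18 (5.01 ± 0.42) and KRT8 (2.98) rose and E-cadherin CDH1 (-4.28) fell, within an epithelium and placode list that was not called (adjusted p = 0.451). In all 1222 genes were higher and 1077 lower. The count was 1524 without control B, 1300 without dox B, 1055 with close pairs summed and 3485 with the library set as a covariate. In every fit without 1 library 86 of 121 named calls held.

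Dox in 3xKO melanoblasts gave MMP1 its largest change, 9.87 ± 0.83 (108 ± 36.2 against 0.114 ± 0.0754 CPM, adjusted p = 3.26e-08). MAPK genes rose in 21 of 29 cases and fell in 0, 24 when adjusted over the list alone (median 2.05, camera adjusted p = 4.13e-28, and 1.00e-08 with an estimated correlation), with SPRY4 at 2.01 ± 0.30, DUSP6 at 2.05 ± 0.46 (332 ± 114 against 80.0 ± 30.6 CPM), EGR1 at 5.63 and IER3 at 4.16 ± 0.39. Senescence-associated secretion had 15 of 23 higher and 0 lower, AREG (7.16) among them (adjusted p = 8.18e-16, and 0.00121 with an estimated correlation; 17 and 1 when adjusted over the list alone). Neuron genes fell in 8 of 24 cases, NEUROG1 by 8.12 on the log2 scale and NHLH1 by 6.59 (adjusted p = 4.93e-09, and adjusted p = 0.320 with an estimated correlation). Antigen presentation had 5 of 17 higher, PSMB8 (4.68) and TAP2 (1.90) included, and 9 with 1 lower when adjusted over the list alone (adjusted p = 1.59e-05, and adjusted p = 0.320 with an estimated correlation). Extracellular matrix had 8 of 22 higher (adjusted p = 4.95e-06, and adjusted p = 0.0875 with an estimated correlation). Pigmentation genes had 9 of 30 lower, such as MLANA (-5.02 ± 0.94), and RAB27A higher (1.26), with a list call (adjusted p = 4.94e-06, and adjusted p = 0.442 with an estimated correlation) that ended without control A (adjusted p = 0.112), 1 of the libraries that stood apart. CDKN1A rose by 2.22 ± 0.30 (54.3 ± 14.5 against 11.7 ± 2.35 CPM), PHLDA3 by 1.83 ± 0.23 and XPC by 1.24. In all 846 genes were higher and 768 lower. The count was 823 and 797 without control B and C, 902 and 917 without dox A and C, 253 with close pairs summed, 2613 with the library set as a covariate and 2551 without the libraries that stood apart. Across the fits without 1 library, 70 of 98 named calls held.

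**Figure D4:**
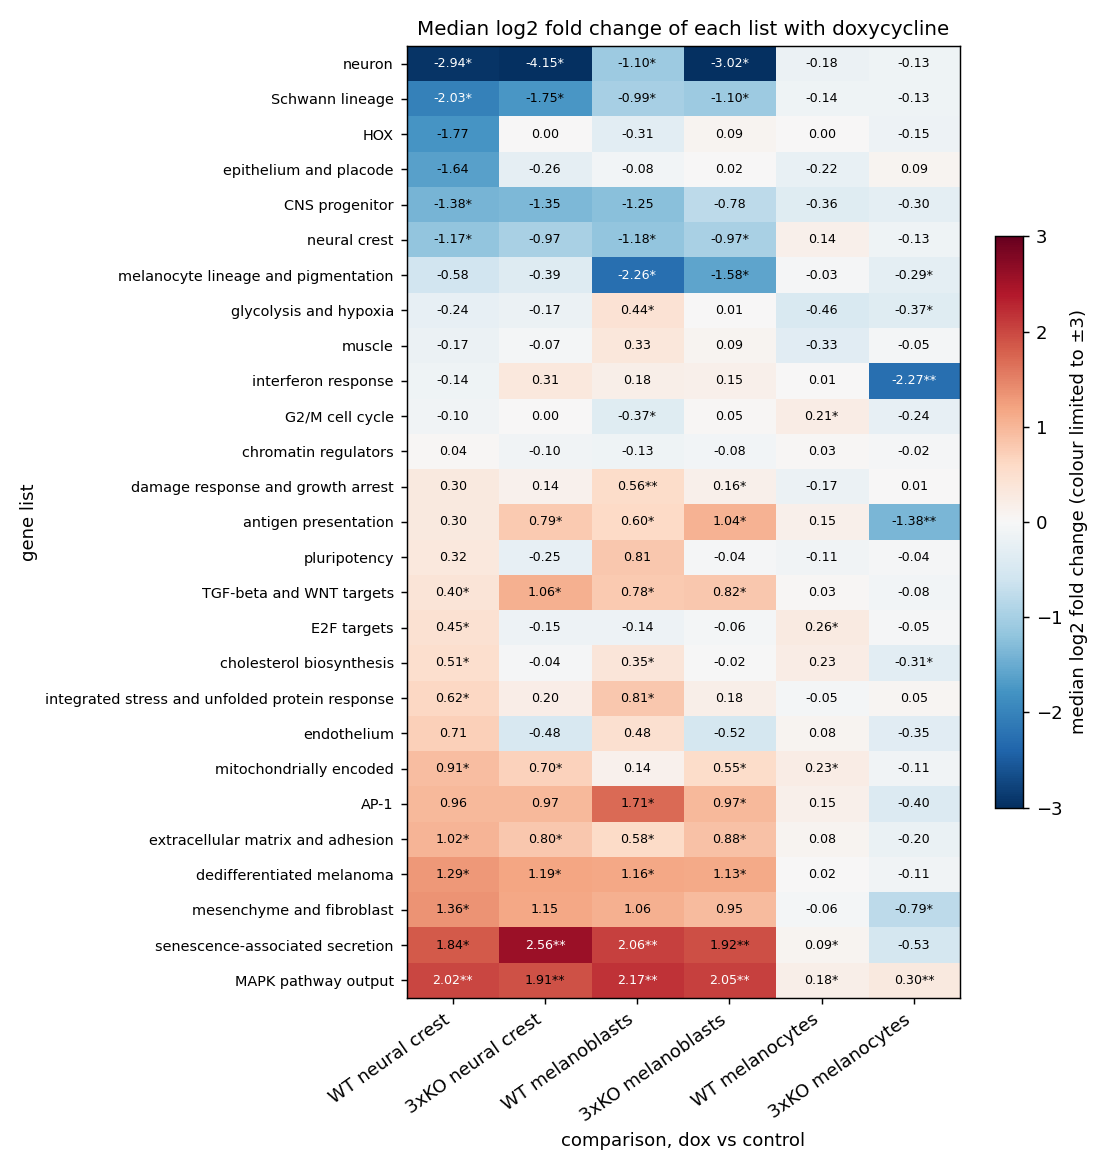
Colour is the median log2 change with dox of each of the 27 gene lists in the 6 comparisons of dox with control, with 1 star for a camera adjusted p under 0.05 and 2 stars where an estimated correlation also gave under 0.05. MAPK output is high in neural crest and melanoblasts of both genotypes (medians 1.91 to 2.17) and lower in melanocytes (0.18 in WT and 0.30 in 3xKO, the latter with 2 stars), and interferon genes are low in 3xKO melanocytes (-2.27).

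With dox in WT melanocytes no MAPK output gene was called higher. The spread used for these tests came from the whole model, so a missing call does not show that a gene did not respond. DUSP6 differed by 0.42 ± 0.45 (43.9 ± 3.54 against 32.8 ± 4.39 CPM, adjusted p = 0.795) and SPRY4 by 0.37 ± 0.29 (66.3 ± 4.57 against 51.1 ± 1.80 CPM, adjusted p = 0.648). Of 29 MAPK genes 0 rose and 1, SPRED1, fell (-0.70 ± 0.21, adjusted p = 0.0441), and the list median was 0.18 (camera adjusted p = 0.0351, and adjusted p = 0.580 with an estimated correlation). That list call ended without control A, control C, dox A or dox B (adjusted p = 0.0814, 0.0716, 0.0519 and 0.0520). MMP1 rose by 3.83 ± 0.73 (3.05 ± 0.243 against 0.211 ± 0.185 CPM, adjusted p = 0.00517) and the membrane protein CDCP1 by 2.97 ± 0.78 (9.56 ± 0.513 against 1.22 ± 0.268 CPM). Far more genes were lower (1039) than higher (27), such as the bicarbonate transporter SLC4A7 (-1.66 ± 0.22, 2.04 ± 0.573 against 6.42 ± 1.41 CPM, adjusted p = 3.53e-04), the ER membrane subunit EMC2 (-1.92 ± 0.33), the kinesin KIF5B (-1.68) and RB1 (-1.49 ± 0.30, 4.23 ± 1.84 against 11.9 ± 3.56 CPM, adjusted p = 0.00663). Across genes the change followed transcript GC content (Spearman 0.49), with a median GC of 41.0% in lower genes and 51.5% in genes not called. With offsets for GC the count was 180 (52 higher, 128 lower). Without control B or dox C 1 gene was called, without dox A 35, without control C 628, and 903 without control A. Close pairs summed, none of them melanocytes, gave 161, and a model of these 2 groups 3668, of which 1475 were higher and 2193 lower. Of 27 named calls 1 held without any 1 library, and RB1 was not called without control B, dox A or dox C (adjusted p = 0.144, 0.0695 and 0.131).

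**Figure D5:**
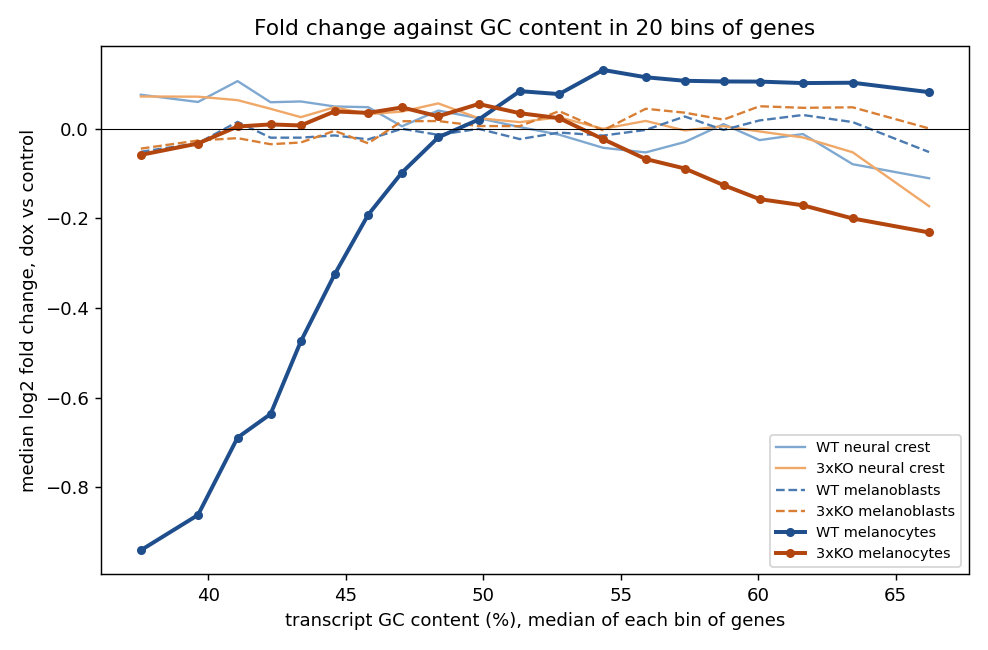
Points are the median log2 change with dox of genes in 20 bins of transcript GC content (percent) for the 6 comparisons of dox with control. In WT melanocytes the median runs from -0.94 in the bin at 37.5% GC to 0.08 at 66.2%, and the other comparisons are flatter.

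In 3xKO melanocytes dox lowered interferon genes. OAS2 changed by -3.62 ± 0.73 (7.25 ± 6.88 against 89.2 ± 93.2 CPM, adjusted p = 0.0316) and IFI6 by -2.11 ± 0.41 (228 ± 151 against 986 ± 620 CPM, adjusted p = 0.0267). The chemokine CXCL1 changed by -3.97 ± 0.49 (3.74 ± 1.86 against 58.9 ± 16.4 CPM, adjusted p = 8.93e-05) and RELB, an NF-kB subunit, by -2.41 ± 0.31. Of 22 interferon genes 6 fell and 0 rose, and 22 fell when adjusted over the list alone (median -2.27, camera adjusted p = 6.33e-39, and 0.00495 with an estimated correlation). Antigen presentation had 1 of 17 lower, TAP2 (-1.36 ± 0.28), and 12 when adjusted over the list alone (median -1.38, adjusted p = 2.51e-18, and 0.00679 with an estimated correlation). MMP1 rose by 4.59 ± 0.67 (8.92 ± 5.22 against 0.361 ± 0.134 CPM) and AREG by 4.22 ± 0.83. MAPK genes had 0 of 29 called (median 0.30, adjusted p = 1.35e-04, and 0.00735 with an estimated correlation), with list levels of 4.70, 5.85 and 5.04 log2 CPM in control A, B and C and 5.88, 6.04 and 5.49 in dox A, B and C, DUSP6 being at 0.95 ± 0.45 (65.7 ± 7.98 against 34.1 ± 10.9 CPM, adjusted p = 0.785). Mesenchyme genes stood lower with 0 of 19 called (median -0.79, adjusted p = 0.00202, and adjusted p = 0.973 with an estimated correlation), a call that ended without control B, control C or dox A (adjusted p = 0.952, 0.0811 and 0.827). In the B pair their median log2 CPM went from 7.07 to 4.67 as that of interferon genes went from 6.97 to 4.43; in the A and C pairs it went from 1.89 to 1.64 and from 4.76 to 4.27 as interferon went from 4.66 to 2.03 and from 4.38 to 1.94. Pigmentation genes stood lower with 0 of 30 called (median -0.29, adjusted p = 0.0186, and adjusted p = 0.973 with an estimated correlation), which ended without control A, control C or dox B (adjusted p = 0.281, 0.127 and 0.893). In all 6 genes were higher and 28 lower. The count was 22 and 201 without control A and B, 17 and 13 without dox A and C, 99 with DESeq2, 175 with libraries paired in column order and 0 in a model of these 2 groups (edgeR, 985 genes with an unadjusted p under 0.05 in the full model). Without any 1 library 5 of 18 named calls held, CXCL1, RELB and MMP1 among them.

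Whether the dox response differed between genotypes was tested by interaction. In neural crest 1 gene was called, the RNA editing enzyme ADARB1 (1.63 ± 0.27 more in 3xKO, adjusted p = 0.0340); that call was lost with RLE scaling, no filter, close pairs summed or only these 4 groups, and in 10 of 12 fits without 1 library, all but those without WT dox D (12 genes) or 3xKO dox A. Of the 10, 9 gave 0 genes and that without WT control A 1 other gene. In melanoblasts edgeR called 0 genes, with 782 at an unadjusted p under 0.05, and DESeq2 called 25. Without the libraries that stood apart the count was 524, without WT control C 87, without 3xKO control A 14, and without WT dox A or B 1. In melanocytes 8 genes were called, 4 higher and 4 lower in 3xKO, with COG6 at 1.77 ± 0.31 and, on the lower side, CXCL1 at -3.91 ± 0.65 and RELB at -2.79 ± 0.42 (adjusted p = 0.00630). With RLE or upper-quartile scaling the numbers were 1 higher and 3 lower. The count was 1 without WT control B, WT dox C or 3xKO control A, 3 without WT dox A, 4 without WT control C or 3xKO dox C, 333 without 3xKO dox A, 434 without WT dox B and 2528 (2250 higher, 278 lower) without 3xKO control B. It was 1053 (983 higher, 70 lower) without the farthest 3xKO libraries, 1707 (1532 higher, 175 lower) with 3xKO libraries paired in column order and 13 with GC offsets. The change followed transcript GC content across genes (Spearman -0.51). Interferon genes had 0 of 22 called in that interaction and 11 lower when adjusted over the list alone (median -2.08, adjusted p = 1.12e-15, and adjusted p = 0.138 with an estimated correlation).

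Between stages of 3xKO cells, the dox response of melanocytes was smaller than that of melanoblasts for MAPK output. SPRY4 differed by -1.63 ± 0.42 (adjusted p = 0.0245), IER3 by -4.36 ± 0.50 (adjusted p = 9.00e-06), CCND1 by -1.22 ± 0.35 (adjusted p = 0.0485) and CDKN2B by -4.65 ± 1.02, while DUSP6 was not called (-1.11 ± 0.63, adjusted p = 0.456). Of 29 MAPK genes 10 were lower and 0 higher, 17 when adjusted over the list alone (median -1.40, camera adjusted p = 3.84e-17, and 1.07e-06 with an estimated correlation). Senescence-associated secretion had 11 of 23 lower, CXCL1 by -6.70 ± 0.72 (adjusted p = 3.47e-14, and 0.00249 with an estimated correlation). Antigen presentation had 9 of 17 lower, PSMB8 by -5.34 (adjusted p = 4.93e-16, and 0.00886 with an estimated correlation). Extracellular matrix had 7 of 22 lower, ITGA5 by -2.29 (adjusted p = 5.70e-07, and 0.0396 with an estimated correlation). Interferon genes had 5 of 22 lower (adjusted p = 5.57e-14, and adjusted p = 0.0901 with an estimated correlation). Melanocytes against neural crest gave a like picture, with 13 of 29 MAPK genes lower (median -1.58, adjusted p = 4.67e-15, and 3.31e-06 with an estimated correlation) and 6 of 24 neuron genes higher (median 4.02, adjusted p = 1.55e-11, and adjusted p = 0.198 with an estimated correlation). The first interaction called 149 genes higher and 385 lower, the second 444 and 525. BRAF itself was not called in the first (-0.46 ± 0.45, adjusted p = 0.7499). Melanoblasts against neural crest gave 0 genes with edgeR, 212 at an unadjusted p under 0.05 and 0 with DESeq2. There melanoblast control B and C and dox A and C lay near neural crest libraries on the principal components. The first count was 245 and 263 without melanoblast control B and C, 328 and 345 without melanoblast dox A and C, 852 without melanocyte control B, 1143 with 3xKO melanocytes paired in column order and 52 in a model of these 4 groups. The second was 585 and 638 without neural crest control B and C, 580 without neural crest dox C, 1866 with that pairing, and 231 with close pairs summed. Named calls held without any 1 library in 40 of 67 cases in the first, where SPRY4 and CCND1 lost theirs, and in 54 of 75 in the second.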

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

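In this part the tests on other splits of the libraries, the interactions and the fits without 1 library were fixed before their results were seen, the test on GC content was written down after the pattern but before its own result, and the other tests of the first 3 patterns were chosen only after the pattern had been seen. Genes lower with dox in WT melanocytes numbered 1039 against 27 higher, and they were AT-rich. BRAF RNA itself had a log2 change of -0.25 ± 0.33 (adjusted p = 0.861), which cannot tell whether the oncogene acted, since in the smaller set of 3xKO neural crest BRAF was at -0.35 while DUSP6 was at 3.47. Tests of how the libraries differ showed that 94.9% of the lower genes had their highest control value in control B (35.5% of other genes), the count was 1 without control B or dox C, and GC offsets kept 12.2% of the lower genes and took their median from -1.07 (median SE 0.276) to -0.45 (median SE 0.188). The pattern is therefore consistent with a technical difference tied to GC content in a few libraries, and a response to dox or BRAFV600E stays open.

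HOX genes stood lower in 3xKO than in WT melanoblast controls, with a median log2 change of -4.80 (24 genes, 0 called). HOXB2, a hindbrain patterning gene, was under 1 CPM in 8 of 12 WT neural crest and melanoblast libraries (at most 0.0873) and all 12 3xKO libraries (at most 0.0850). The other 4 WT libraries, those that stood apart, had 8.25 CPM or more. Without the set-apart libraries the median was 1.32. This and the 8 low WT libraries argue against genotype alone, but no 3xKO library was high. The 4 high WT libraries could differ in body axis position. Whether cultures, handling or date differed cannot be read from the labels.

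Interferon genes stood high in 3xKO melanocyte controls, with 21 of 22 higher and a median log2 change of 5.59. A single library does not carry the list, since 21 of the 21 genes were still called without the libraries farthest from their groups, and 21 of 22 had every 3xKO control above every WT melanocyte library, as had 28.1% of the other genes tested. Contaminating mesenchymal cells are argued against in control A only, whose mesenchyme median (1.89 log2 CPM) was below those of WT controls. They stay open in C (4.76) and B (7.07). Interferon differences from WT were 4.07, 4.11 and 6.42 in A, C and B. The genotype, the lentivirus of the protocol and culture conditions could not be tested with these labels and stay open.

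Some levels in WT neural crest with dox (n = 4) had 1 library far off. Of 40 values tested 8 passed the limit on gap over range. The ratio was 1 for the neuronal or crest regulators NEUROG1, PRDM12, SOX3 and SOX21. It was 0.956 for PPP1R17, 0.942 for SMOC1, 0.912 for TYR and 0.886 for DUSP6. The chance rate of 1 in 20 needs independent libraries, and dox A and C were a close pair.

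A difference in dox response between groups was tested by interaction, and these results were marked by that test. The dox by genotype interaction called 1 gene in neural crest and 8 in melanocytes. Between 3xKO melanocytes and melanoblasts 534 genes were called, with SPRY4 at -1.63, CDKN1A at -1.68, CDKN2B at -4.65 and CCND1 at -1.22. Between 3xKO melanocytes and neural crest the number was 969, with SPRY4 at -1.97, CDKN2B at -4.95 and CCND1 at -1.92. Against melanoblasts SPRY4 lost its call without melanoblast control A, dox A, dox C or melanocyte dox C (adjusted p from 0.0549 to 0.0762), and CCND1 in 9 of 12 fits without 1 library (0.0698 to 0.133).

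Other splits of the same libraries into groups were counted for 10 of the 2-group comparisons, 10 splits each, too few for a share under 0.05. The real split, itself counted, was the only one with as many genes (1 of 10) in melanocytes against melanoblasts for WT control (12113 genes, highest other 0) and 3xKO dox (9345, highest other 963), in 3xKO against WT melanocytes (8361, highest other 4219), and with dox in WT melanoblasts (2299, highest other 18), WT melanocytes (1066, highest other 0), 3xKO neural crest (2389, highest other 0) and 3xKO melanoblasts (1614, highest other 1). It was 2 of 10 in 3xKO against WT melanoblasts (762, highest other 1157) and 6 of 10 with dox in 3xKO melanocytes (34, highest other 6976). The last points to a structure of the samples, in which control B and dox B together stood far out, with control A and dox A on the other side. In 3xKO dox melanoblasts against neural crest 0 genes were called (highest other 0), which all 10 splits reach whatever the data.

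For the interactions 24 drawn splits were counted. The dox by genotype interaction of melanoblasts (highest other 1573) and the dox by stage interaction of melanoblasts against neural crest (highest other 74) had 0 genes, which all 24 splits reach whatever the data. For the other 3, chance was not excluded in the model without pairs. As many genes came from 2 of 24 in the dox by genotype interaction of melanocytes (8 genes, highest other 818), 8 of 24 in the dox by stage interaction of melanocytes against melanoblasts (534, highest other 4282) and 7 of 24 in that against neural crest (969, highest other 4080). With 3xKO melanocytes paired in column order these counts were 1707 (1532 higher, 175 lower), 1143 and 1866, and no splits were counted in that fit. The first interaction followed GC content across genes (Spearman -0.51).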

How the results depend on the processing

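Tests with close pairs summed, with a library-set covariate, with 3xKO melanocyte libraries paired in column order, with GC offsets, and without libraries that stood apart or lay farthest from their group were chosen only after the results had been seen. No paired analysis was possible over the whole design because the columns of the count table carry no replicate numbers that tie a dox library to a control library. For 3xKO melanocytes alone a fit paired in column order was run, a pairing read from the values, where deviations of control and dox libraries correlated at 0.863, 0.862 and 0.682 within those pairs and negatively in every other combination. Pseudocounts of 0.5 and 5, fold changes with no filter on low values, and a count test on recovered reads were not run because the values were counts already. Of 2694 gene results, called or not, 2672 stayed the same with RLE scaling and 2659 with upper-quartile scaling. The number was 2666 with no filter, 2329 with close pairs summed, 2516 with the covariate and 2506 with GC offsets. Other settings could not be run for each result. The stricter filter kept 2575, DESeq2 2491 and models of only the compared groups 2142. Without the libraries that stood apart 1829 were kept (199 stronger, 80 weaker). Without the farthest 3xKO melanocyte libraries it was 780 (26, 66) and with 3xKO melanocytes paired 806 (64, 4). Close pairs summed lost (weaker) 364 calls, models of only the compared groups 239 and GC offsets 102. The cause was not tested. Leaving out 1 library kept 19011 gene results, made 1305 weaker and 280 stronger, and reversed 1. For lists, 192 of 513 results were called, of which 21 kept the call with an estimated correlation and 171 lost it. With fry 378 stayed the same (105 weaker, 30 stronger) and with RLE scaling 504. It was 505 with the stricter filter, 483 with close pairs summed and 487 with the covariate. Of fewer results 355 stayed without the libraries that stood apart (27 weaker, 22 stronger, 1 reversed). It was 154 without the farthest libraries (7, 1) and 158 with 3xKO melanocytes paired (2, 2). Without 1 library 3667 list results were kept, 212 were weaker, 112 stronger and 5 reversed.

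Directions reversed in these cases, and the cause was not tested. With GC offsets in WT melanocytes against melanoblasts the log2 change became 0.47 for RB1, 1.18 for MDM2, -0.92 for SPRY4, 0.23 for EDNRB, 0.47 for ETV1, 0.11 for CCNG1, 0.60 for SESN1, -0.00135 for TUBB3 and -0.0684 for IRF7. Of these RB1, MDM2 and SPRY4 were called in the opposite direction (adjusted p = 0.00513, 0.00378 and 0.0257). It became -0.0811 for JUND in 3xKO melanocytes against melanoblasts, and -0.32 for RRM2B, -0.58 for SESN1 and -0.24 for SC5D in 3xKO against WT melanocytes. PAX6 with dox in WT neural crest ran from -6.18 without WT dox D to 0.69 without WT control B. The HOX median in WT melanoblasts against neural crest ran from -4.71 without melanoblast control C to 4.63 without neural crest control B. In 3xKO against WT melanoblasts it ran from -5.33 without WT control B to 0.83 without WT control C, and it was 1.32 without the libraries that stood apart. In the dox by genotype interaction of neural crest it ran from -1.88 without WT control B to 4.02 without WT dox D. Mesenchyme genes in 3xKO melanocytes with dox had a median from -1.32 without control A to 0 without control B, and -0.50 without dox A, where the direction of the test turned. Glycolysis genes in the dox by genotype interaction of neural crest ran from -0.12 without 3xKO control A to 0.45 without WT dox D.

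Numbers of changed genes moved over 1.5-fold in these fits, and the cause was not tested. In WT melanoblasts against neural crest (116) DESeq2 gave 357, only the compared groups 0 and close pairs summed 0. The covariate gave 489, GC offsets 213, leaving out the libraries that stood apart 1398, and leaving out 1 library 0 to 1028. Melanocytes against melanoblasts stayed within 1.5-fold in WT (12113, 11438 to 11769) and 3xKO (9345, 7741 to 9606). GC offsets kept 7213 and 6862 of these calls. In 3xKO dox melanoblasts against neural crest (0) DESeq2 gave 13, and 1 library left out 0 to 1. For 3xKO against WT in neural crest (138) DESeq2 gave 356, only the compared groups 685, close pairs summed 30, the covariate 497 and GC offsets 302, with 30 to 86 without 1 library. In melanoblasts (762) the same settings gave 1308, 394, 51, 1833 and 1578, leaving out the libraries that stood apart 3344, and leaving out 1 library 203 to 1693. In melanocytes (8361) only the compared groups gave 4747, and 1 library left out 6031 to 9552.

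For dox against control in WT neural crest (2542) close pairs summed gave 1268, and leaving out 1 library 1100 to 4160. WT melanoblasts (2299) had 1055 with close pairs summed, 3485 with the covariate, and 1300 to 2418 without 1 library. WT melanocytes (1066) had 3668 with only the compared groups, 161 with close pairs summed, 180 with GC offsets, and 1 to 1330 without 1 library. The model of 3xKO neural crest (2389) gave 3703 with only the compared groups, 749 with close pairs summed and 1529 to 2058 without 1 library. In 3xKO melanoblasts (1614) close pairs summed gave 253, the covariate 2613, leaving out the libraries that stood apart 2551, and leaving out 1 library 797 to 1797. In 3xKO melanocytes (34) DESeq2 gave 99, only the compared groups 0, close pairs summed 6, the covariate 94, GC offsets 56, pairing in column order 175, and leaving out 1 library 13 to 201. The cause was not tested.

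For the dox by genotype interaction in neural crest (1) RLE scaling gave 0, no filter 0, DESeq2 13, only the compared groups 4, close pairs summed 0, the covariate 10, GC offsets 6, leaving out the libraries that stood apart 27, and leaving out 1 library 0 to 12. In melanoblasts (0) DESeq2 gave 25, the covariate 18, GC offsets 1, leaving out the libraries that stood apart 524, and leaving out 1 library 0 to 87. In melanocytes (8) RLE scaling gave 4, upper-quartile scaling 4, no filter 4, the stricter filter 14, DESeq2 180, only the compared groups 0, close pairs summed 2, the covariate 162, GC offsets 13, leaving out the farthest libraries 1053, pairing in column order 1707, and leaving out 1 library 1 to 2528. The dox by stage interaction of melanoblasts against neural crest (0) stayed at 0 in every fit. That of melanocytes against melanoblasts (534) went to 910 with DESeq2, 52 with only the compared groups, 80 with close pairs summed, 1101 with the covariate, 1568 without the libraries that stood apart, 1143 with pairing in column order, and 245 to 852 without 1 library. That of melanocytes against neural crest (969) went to 1458 with DESeq2, 594 with only the compared groups, 231 with close pairs summed, 1837 with the covariate, 1493 with GC offsets, 1784 without the libraries that stood apart, 1866 with pairing in column order, and 580 to 1301 without 1 library. The cause was not tested.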

Other observations

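In this part the values within sets of libraries were chosen only after the set structure had been seen, and the rest follows the tests fixed earlier. From melanoblasts to melanocytes 7 of 11 pluripotency genes were lower and 0 higher in WT control, with no list call (median -2.21, camera adjusted p = 0.0702), and 7 were lower and 1 higher in 3xKO dox (median -2.34, adjusted p = 0.0319). The latter was not called with an estimated correlation (adjusted p = 0.331) or without melanocyte dox B (adjusted p = 0.0640). CNS progenitor genes had 6 of 14 lower and 2 higher with dox in WT neural crest (median -1.38, adjusted p = 0.0460, and adjusted p = 0.239 with an estimated correlation). That call ended without control B, dox B or dox D (adjusted p = 0.158, 0.0557 and 0.0930).

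Levels by stage set the frame for the dox responses. In WT controls SOX10 stood at 482 ± 162 CPM in neural crest (n = 2), 398 ± 76.8 in melanoblasts and 1378 ± 111 in melanocytes, and in 3xKO controls at 113 ± 33.04, 183 ± 29.1 and 1171 ± 793 CPM. PMEL reached 60840 ± 3045 CPM in WT melanocyte controls and 26130 ± 16990 CPM in 3xKO. MITF was at 65.6 ± 10.3 CPM in WT and 216 ± 63.2 CPM in 3xKO melanocyte controls, a log2 difference of 1.72 ± 0.72 (adjusted p = 0.0460). Each of 5 of the 6 libraries, left out, ended that call. CDKN2B, a CDK4/6 inhibitor next to CDKN2A, rose with dox in 3xKO melanoblasts by 5.24 ± 0.83 (adjusted p = 1.09e-04).

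Values within the 2 sets of libraries are given here without a test of their difference. DUSP6 changed with dox by 2.70 in the larger and 1.94 in the smaller set of WT neural crest, 2.22 and 2.13 in WT melanoblasts, 2.29 and 3.47 in 3xKO neural crest and 2.03 and 2.16 in 3xKO melanoblasts. SPRY4 differed by 3.67 and 3.51, 3.32 and 3.31, 2.15 and 3.09, and 2.05 and 1.88 in the same order, and SOX10 by -5.95 and -4.44, -2.46 and -3.79, -4.47 and -2.71, and -3.38 and -0.42. CCND1 was at 1.60 and 2.75 and ETV5 at 0.03 and 1.67 in 3xKO neural crest. No test could be made within the smaller sets of 1 library per group.

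Pairs of libraries in 6 cases differed by 1.99 to 3.65 times counting noise, while the other 31 pairs differed by 5.57 to 338 times. Such pairs could be divided from 1 culture, in which case the p-values of their groups are too small; summing them took the count with dox in 3xKO melanoblasts from 1614 to 253. With no dox group lacking the cassette, dox and BRAFV600E effects are not separable. A culture-level replicate number, cells without the cassette and reads over the transgene would separate these readings.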
